A study of Homo sapiens with 2 samples.

How the data were processed

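RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised to one-colour Affymetrix arrays, per the labels' protocols. The series holds 2 arrays of AGS gastric cancer cells, 1 labelled control and 1 labelled galectin-3 silenced, and each array was placed in its group by its title. The deposited values are intensity values on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The software version, the scaling target and any filters are not given in the sources used here. The values themselves show that both arrays had been brought to the same mean, with a 2% trimmed mean of 500.07 on each. Because these means lay within 10% of each other, the deposited scaling was kept. MAS5 summarises each probe set on each array by itself, so low signals are noisy, and scaling to a common mean hides any change in total RNA per cell.

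Probe sets were named from a table of the platform's annotation. It lists 42898 of the 54675 probe sets, of which 41097 carry 1 gene symbol and 1801 carry several, and the other 11777 are unnamed here. By gene identifier 41043 were matched to the RefSeq gene table of assembly GRCh38.p14, and 0 symbols had to be updated. Probe sets with several symbols or with no symbol named no gene, which left 19775 genes. Genome coordinates were not used here.

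A floor was set on each array at the 95th percentile of 135 probe sets for olfactory receptor genes, which a stomach cell line is not known to use. It was 138.4 on the control array and 109.5 on the silenced array. Above it were 21010 probe sets (38.4%) on the control array and 22939 (42.0%) on the silenced array. Signals below the floor were raised to it, so a gene under the floor on 1 array has a ratio that is a bound, and a gene under it on both arrays has none. Because the floors differ, 352 of the 935 genes above the floor on 1 array only had a bound with no direction. No fold is given for these, and they stay in list medians at their bound. Each gene took the value of its probe set with the highest mean log2 signal, leaving out probe sets of the cross-hybridising _x_at kind where the gene had another, and whether a gene was above the floor was read from that probe set. In all 10514 genes were measured, 9579 of them above the floor on both arrays. The log2 ratio is the silenced array minus the control array.

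With 1 array per group no test between groups exists. Genes were counted by a rule of size, a log2 ratio of at least 1 in either direction, which is 2-fold. Gene lists are described by their median log2 ratio and its percentile among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean signal. This describes these arrays and is not a test of the conditions. Under the alternatives and in the simulated data fewer random lists were drawn, so percentiles given for an alternative are less precise. For 30 lists, 28 had at least 3 measured members and so a median. By construction 5% of random lists lie outside the central 95%.

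The genes named follow a rule. It takes LGALS3, the 10 highest and 10 lowest genes above the floor on both arrays with 2 or more such probe sets going the same way, the 5 highest and 5 lowest with a single probe set, and the 3 highest and 3 lowest bounds repeated by another probe set. In each list it takes up to 4 members past 2-fold with the largest ratios, or the 2 largest where none passed, and 7 preset genes from the galectin-3 literature. Symbols starting with LOC were left out. Any other gene named was chosen after its value was seen. The groups, the rule of size, the floor, the 30 lists, the rule for named genes and most alternatives were fixed before the data were examined.

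Technical spread was described from the arrays' own controls and from genes with several probe sets. The 18 hybridization control probe sets above the floor had a median log2 ratio of -0.18 (SD 0.09 over probe sets) and the 19 poly-A control probe sets 0.23 (SD 0.23). The probe sets for the 3', middle and 5' parts of GAPDH and ACTB had medians of -0.08 and -0.04, which ran from -0.31 to 0.10 for GAPDH and from -0.27 to 0.14 for ACTB over 6 other scalings and so have no settled direction. In 4728 genes with 2 or more probe sets above the floor on both arrays, the SD of the log2 ratio between probe sets of one gene was 0.32. This measures probe sets on the same RNA and not repeat cultures.

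The procedure was tested on simulated data, with 10445 genes given a normal spread with the observed robust SD of ratios, and 200 a known change. These 200 had a mean log2 signal of at least 9, so calls at weaker signals were not tested. Both simulated arrays were drawn around a common mean per probe set, so the unequal floors of the real arrays were not reproduced. Of the genes given a log2 change of 1.5, 92% were called at least 2-fold higher, and 98% of those given -1.5 were called lower. All of those given 2 or -2 were called. Among the unchanged genes 224 (2.19%) also passed 2-fold. Of 100 lists of 30 unchanged genes 5% lay outside the central 95%, and all 50 lists shifted by 0.5 lay above the upper bound. These lists were drawn at random from genes with independent noise, so about 5% follows by construction. They do not show how often a list of genes regulated together would lie outside. No shift smaller than 0.5 was simulated, whereas most list medians reported below as outside their central 95% were smaller in size than that.

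Alternatives were median centring, quantile normalization, a lowess curve, other floors, no floor, the floor as an offset, the median of a gene's probe sets, leaving out _s_at and _x_at probe sets, other rules of size, and random lists not matched on signal. Scaling on the hybridization or poly-A controls was added after the data were seen. The planned lowess curve was first fitted only on probe sets above the floor. After its counts were seen it was replaced by a curve over all probe sets, and the first form was kept as an added alternative. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Of the probe sets with several names or none, only their number past 2-fold is reported.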

Results

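Gene expression was measured in AGS cells, an epithelial cell line from a human gastric adenocarcinoma, in which galectin-3 had been silenced with a small interfering RNA. Galectin-3, encoded by LGALS3, is a lectin that binds beta-galactosides and is found in the nucleus, in the cytoplasm and outside the cell. There were 2 one-colour Affymetrix arrays, 1 from control cells and 1 from silenced cells, each with 54675 probe sets. How the control cells were treated is not given in the sources used here. The comparison asked which genes differ in expression when galectin-3 is silenced. The log2 signals of the arrays correlated with r = 0.915 across all probe sets and r = 0.945 across the 23611 probe sets above the background floor on at least 1 array. These are correlations across probe sets, which are not independent replicates. With 1 array per group no difference described here has a replicate check, so no test was made and no p-value is given, and the number of arrays limits the precision of every value.

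LGALS3 itself was 7.48-fold lower on the silenced array. Its signal was 20206 in the control and 2699.8 after silencing, which is 13.4% of the control, with a log2 ratio of -2.90. This was the lowest ratio among all 10514 genes measured. A second LGALS3 probe set was under the floor on both arrays, with signals of 57.8 and 55.6, and gave no ratio.

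**Figure D1:**
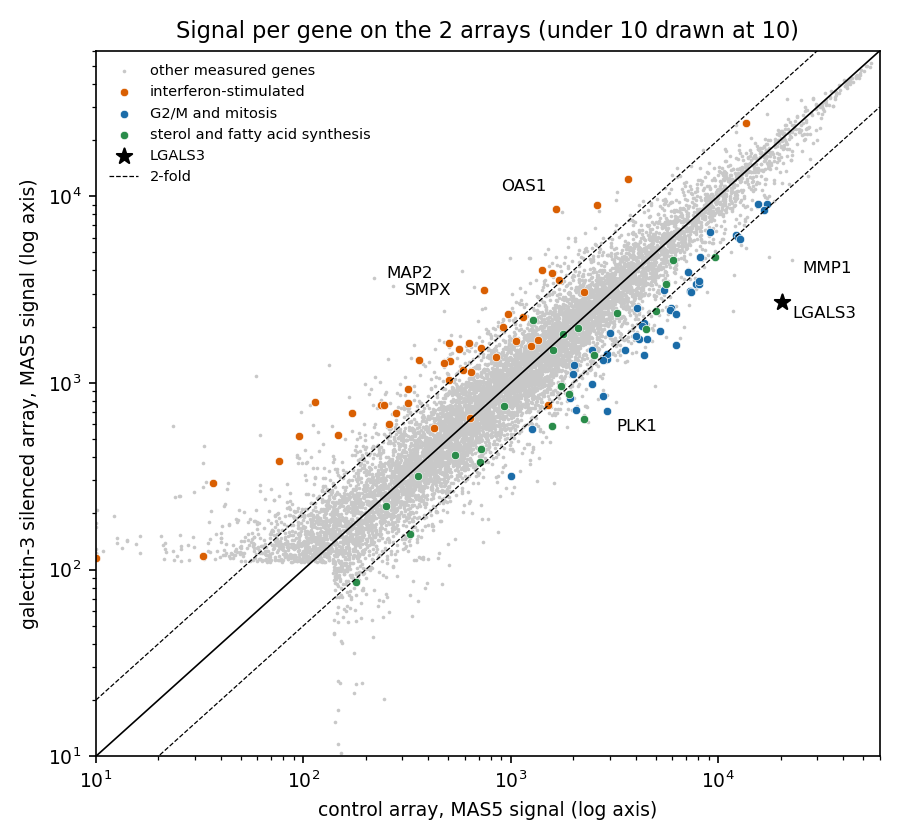
Signal per gene on the control array (horizontal, log axis) and on the galectin-3 silenced array (vertical, log axis), with 1 point per measured gene, signals under 10 drawn at 10 and dashed lines at 2-fold. LGALS3 (star) lies at 20206 on the control array and 2699.8 on the silenced array, most interferon-stimulated genes lie above the diagonal, and all 42 genes of the G2/M list lie below it.

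Silencing of galectin-3 was accompanied by similar numbers of higher and lower genes. By the rule of size, 348 genes were at least 2-fold higher and 323 at least 2-fold lower, together 6.38% of the genes measured. Of these, 26 were at least 4-fold higher and 13 at least 4-fold lower. The balance between directions depended on how the arrays were scaled. Of the genes past 2-fold, 51.9% were higher with the deposited scaling, 75.9% when the hybridization controls were set equal, 22.7% when the poly-A controls were set equal, and 22.4% with a lowess curve fitted only on probe sets above the floor. The spread of the ratios gave a rough comparison for these single-gene differences. Among genes above the floor on both arrays 604 passed 2-fold, while a normal distribution with the observed robust SD (0.49 at the lowest signals, 0.31 at the highest) would place 224 genes there. At the lowest signals 14 genes were higher and 42 lower, beside 39.7 so placed, and at the highest 15 and 26, beside 1.54. The control array's higher floor, 138.4 against 109.5, left less room at the lowest signals for higher genes than for lower ones. Without replicate arrays the spread of the ratios mixes noise with real differences, so 224 is not a count of noise. Other probe sets of the same gene mostly went the same way, though often by less. Among 128 genes at least 2-fold higher with another probe set above the floor on both arrays, all other probe sets were also higher in 115 (89.8%), and the same held in the lower direction for 118 of 127 genes (92.9%). All other probe sets differed by at least 1.5-fold that way in 94 of the higher genes (73.4%) and 81 of the lower genes (63.8%). Among 2273 genes under 1.2-fold either way, the other probe sets went the same way in 52.7%.

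The largest differences among genes with several probe sets above the floor that all went the same way were in genes of several functions. MAP2, a microtubule-associated protein best known from neurons, was 16.7-fold higher, with signals of 218 and 3646. Its second probe set gave a log2 ratio of 2.08. OAS1, an oligoadenylate synthetase induced by interferon, was 5.21-fold higher, ANXA9, an annexin, 5.06-fold, SCEL, a precursor of the cornified envelope, 4.71-fold, and TM4SF1, a membrane glycoprotein, 4.68-fold. NEDD9, a scaffold of adhesion signalling, was 4.63-fold higher, the interferon-induced gene IFIT2 4.22-fold, the cytochrome P450 gene CYP3A5 4.09-fold, ATF7IP2 3.81-fold and the cell adhesion molecule CEACAM1 3.77-fold. In the other direction, REEP3, a protein of the endoplasmic reticulum, was 5.55-fold lower, and RGS5, a regulator of G-protein signalling, 5.41-fold lower. CSRP2, a LIM-domain protein, was 3.88-fold lower, the pseudouridine synthase TRUB1 3.84-fold, the protocadherin PCDH7 3.76-fold and INSIG1, which holds the sterol sensor in the endoplasmic reticulum, 3.54-fold. GSTCD was 3.47-fold lower, the cyclin CCNF 3.45-fold, the actin-associated PDLIM5 3.43-fold and the guanine deaminase GDA 3.39-fold. These folds are those of 1 probe set per gene, and some other probe sets gave much smaller log2 ratios, among them 0.38 for ATF7IP2, -0.16 for GSTCD, -0.55 for TRUB1, -0.63 for PDLIM5, -0.88 for CSRP2 and -0.96 for REEP3.

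Among genes with a single probe set, SMPX, a small muscle protein, was 12.2-fold higher, with signals of 269.8 and 3290. The matrix protease MMP7 was 5.04-fold higher, SLC16A4, of the monocarboxylate transporter family, 4.84-fold, the apolipoprotein APOD 4.20-fold and CALCOCO1 3.76-fold. Lower were XK, a membrane protein of red cells, by 5.23-fold, ID3, an inhibitor of basic helix-loop-helix factors, by 5.18-fold, the collagenase MMP1 by 4.96-fold, the cancer/testis antigen PAGE4 by 4.81-fold and the mitotic regulator PIMREG by 4.51-fold. For some genes the probe set that stood for the gene was above the floor on 1 array only, so that the ratio is a bound. The gluconokinase IDNK was at least 9.02-fold higher on the silenced array, although its other probe set gave a log2 ratio of 0.94. The glucose transporter SLC2A12 was at least 7.91-fold higher and the interferon-induced DNA sensor IFI16 at least 5.71-fold. Another IFI16 probe set, above the floor on both arrays, gave a smaller log2 ratio of 1.93, with signals of 148.5 and 567.6. The protease PRSS12 was at least 3.51-fold lower, the acyl-CoA thioesterase ACOT11 at least 2.08-fold and the transcription factor subunit TAF4B at least 1.69-fold.

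Interferon-stimulated genes were higher as a group on the silenced array. Of 43 measured genes, 30 were at least 2-fold higher, 0 were at least 2-fold lower and 13 passed in neither direction. The median log2 ratio was 1.28, above all 10000 random lists matched on signal, whose central 95% ran from -0.17 to 0.15. IFI16 was at least 5.71-fold higher on 1 probe set and had a log2 ratio of 1.93 on another. OAS1 was 5.21-fold higher, IFIT2 4.22-fold and the chemokine CXCL11 3.99-fold, with CXCL11 signals of 171.8 and 685.8. The list holds sensors of viral RNA, antiviral effectors and chemokines, which were not counted apart. OAS3 went the other way, with a log2 ratio of -0.998 that stopped just short of 2-fold, and was singled out after its value was seen. Of 10 markers on the array for leukocytes, which can be a source of such transcripts, 9 were under the floor on both arrays and gave no ratio. The other was LYZ, with signals of 25668 and 27270, and this gene is also expressed by gastric epithelium.

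Genes of mitosis were lower as a group. All 42 measured genes of the G2/M list had a ratio under 0, 29 of them at least 2-fold lower, and 0 were at least 2-fold higher. The median log2 ratio was -1.18, below all 10000 random lists. PLK1, a mitotic kinase, was 4.08-fold lower, the spindle protein DLGAP5 3.94-fold, the kinesin KIF20A 3.28-fold and the phosphatase CDC25C, which activates the mitotic cyclin-dependent kinase, 3.17-fold. Genes of the G1/S transition and DNA replication were lower by less. Of 42 measured, 5 were at least 2-fold lower and 1 at least 2-fold higher, with a median log2 ratio of -0.48, also below all 10000 random lists. The DNA polymerase subunit POLA1 was 3.94-fold lower, the replicative helicase subunit MCM3 2.16-fold and the transcription factor E2F7 2.08-fold, although another E2F7 probe set had a log2 ratio of -0.29. TK1 at 2.02-fold and E2F8 at 2.01-fold, named after their values were seen, were the remaining lower genes. The D-type cyclin CCND3 was 2.82-fold higher. The G2/M median lay below the G1/S median by more than in any of 10000 pairs of random lists, with a difference of -0.70 against a central 95% of -0.19 to 0.19.

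Genes of sterol and fatty acid synthesis were lower. Of 23 measured, 7 were at least 2-fold lower, 0 were at least 2-fold higher and 16 passed in neither direction. The median log2 ratio was -0.71, below all 10000 random lists. INSIG1 was 3.54-fold lower, HMGCS1, which makes the precursor used by the rate-limiting enzyme of cholesterol synthesis, 2.68-fold, the sterol methyl oxidase MSMO1 2.32-fold and the reductase DHCR7, which forms cholesterol, 2.21-fold.

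**Figure D2:**
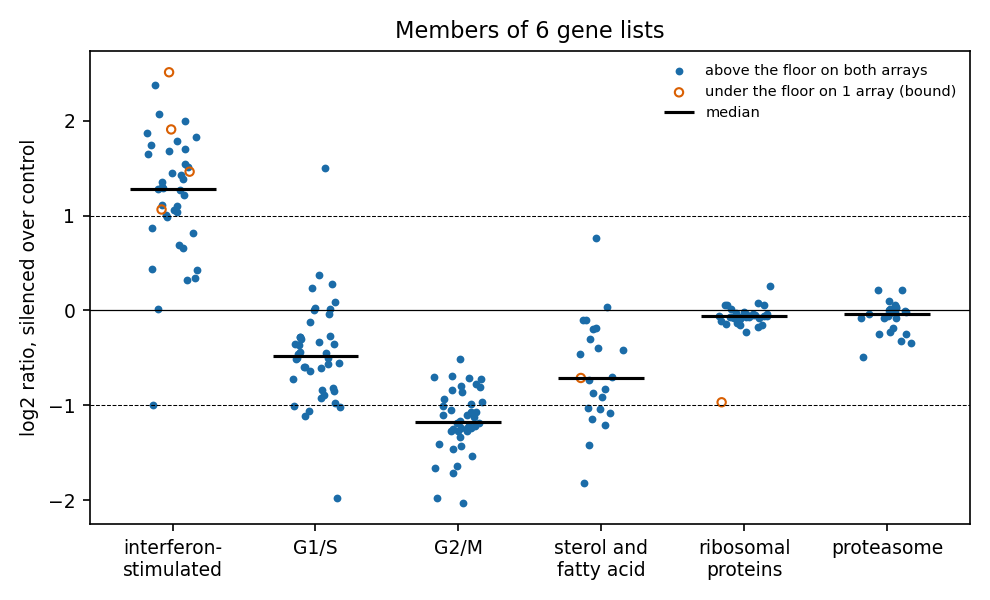
Log2 ratio (silenced over control) of each measured member of 6 gene lists, with filled points for genes above the floor on both arrays, open points for bounds, bars for medians and dashed lines at 2-fold. The 2 interferon-stimulated genes whose bounds gave no direction are left out of the points, and the medians are 1.28 for interferon-stimulated genes, -0.48 for G1/S, -1.18 for G2/M and -0.71 for sterol and fatty acid synthesis.

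Genes linked to galectin-3 in the literature did not move together. Of 28 measured partner and target genes, 1 was at least 2-fold higher and 3 at least 2-fold lower, and their median log2 ratio of -0.06 lay above 24.4% of random lists. MMP1 was 4.96-fold lower, with signals of 22581 and 4555. The apoptosis inhibitor BIRC5 was 2.27-fold lower and the cyclin CCNA2 2.10-fold, and both of these also belong to the G2/M list. MGAT5, the glycosyltransferase that forms branched N-glycans bound by galectin-3, was 2.12-fold higher. CCND1 was 1.86-fold lower and the cyclin-dependent kinase inhibitor CDKN1A 1.83-fold higher, both short of 2-fold, and MYC had a log2 ratio of -0.15. The actin-bundling gene FSCN1, the thrombin receptor F2R and the telomerase gene TERT were under the floor on both arrays. Within the galectin family 7 genes were measured. Apart from LGALS3, LGALS4 was 2.69-fold lower and LGALSL 2.02-fold higher on 1 probe set, with a log2 ratio of 0.47 on another. The family median of 0.76 turned to -0.24 with a floor 2 times higher and to -0.05 with a lowess curve fitted only on probe sets above the floor. With that curve the median of all genes was -0.07, so relative to all genes the family median stayed slightly above 0. Without _s_at and _x_at probe sets it lay above 91.3% of random lists, inside their central 95%.

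Several lists had medians slightly above those of random lists, with few members past 2-fold. Of 21 Wnt target genes 3 were at least 2-fold higher, the growth factor FGF20 by 2.29-fold, the ubiquitin ligase ZNRF3 by 2.27-fold and JUN by 2.14-fold, and NOTUM was at least 2.11-fold lower, with a list median of 0.28 above 99.8% of random lists. Of 26 epithelial junction genes the tight junction gene CLDN4 was 2.12-fold higher and CLDN1 2.42-fold lower, with a median of 0.29 above 99.97% of random lists. Of 34 apoptosis regulators 3 were higher and 2 lower, with a median of 0.24 above 99.6% of random lists. Without _s_at and _x_at probe sets it lay above 95.25%, inside the central 95%. The interferon-induced XAF1 was at least 3.76-fold higher, PMAIP1, which antagonises survival proteins, 3.48-fold and BNIP3L, named after its value was seen, 2.12-fold, while APAF1, a part of the apoptosome, was 2.41-fold lower on 1 probe set and had a log2 ratio of -0.07 on another. Of 30 glycosyltransferases GCNT1 was 2.20-fold and MGAT5 2.12-fold higher and the mannosidase MAN1A1 2.42-fold lower, with a median of 0.24 above 99.5% of random lists. It was inside the central 95% without a floor, above 96.8% of random lists, and with the median of a gene's probe sets, above 96.4%.

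The actin and motility list had 3 of 36 genes at least 2-fold higher. These were RHOB, a small GTPase, by 3.22-fold, the actin-binding TAGLN by 2.86-fold and RHOU by 2.31-fold. Its median of 0.17 lay above 99.9% of random lists, and above 93.7% without _s_at and _x_at probe sets, which is inside the central 95%. It turned to -0.06 with the poly-A controls set equal, a scaling that shifts every gene and put the median of all genes at -0.25. Relative to all genes it was 0.19 with either scaling. Of 17 targets of NF-kB, TNFAIP3 was 2.39-fold and the cytokine LIF 2.22-fold higher. Their median of 0.31, above 98.7% of random lists, turned to -0.07 with a floor 2 times higher and to -0.01 with a lowess curve fitted only on probe sets above the floor. With that curve the median of all genes was -0.07, so relative to all genes the NF-kB median stayed slightly above 0. Without _s_at and _x_at probe sets it lay above 79.4% of random lists.

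The lists for gastric and intestinal differentiation and for the unfolded protein response had medians slightly below those of random lists. In the first 14 genes had a ratio under 0 and 6 above it, and in the second 22 and 9. Of 20 differentiation genes, LGALS4 was 2.69-fold lower, REG4, a secreted lectin-like protein of intestinal cells, 2.47-fold, and ANXA10 at least 2.29-fold. SOX2, a transcription factor of the stomach, was 2.64-fold higher and the mucin MUC13, named after its value was seen, 2.09-fold. The median of -0.35 lay above 0.11% of random lists. It was inside the central 95% with the array median as the floor, above 4.15% of random lists, and without a floor, above 8% of them. Of 31 genes of the unfolded protein and integrated stress responses, the cystathionine lyase CTH was 3.23-fold lower and none was 2-fold higher, with a median of -0.22 above 0.85% of random lists.

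**Figure D3:**
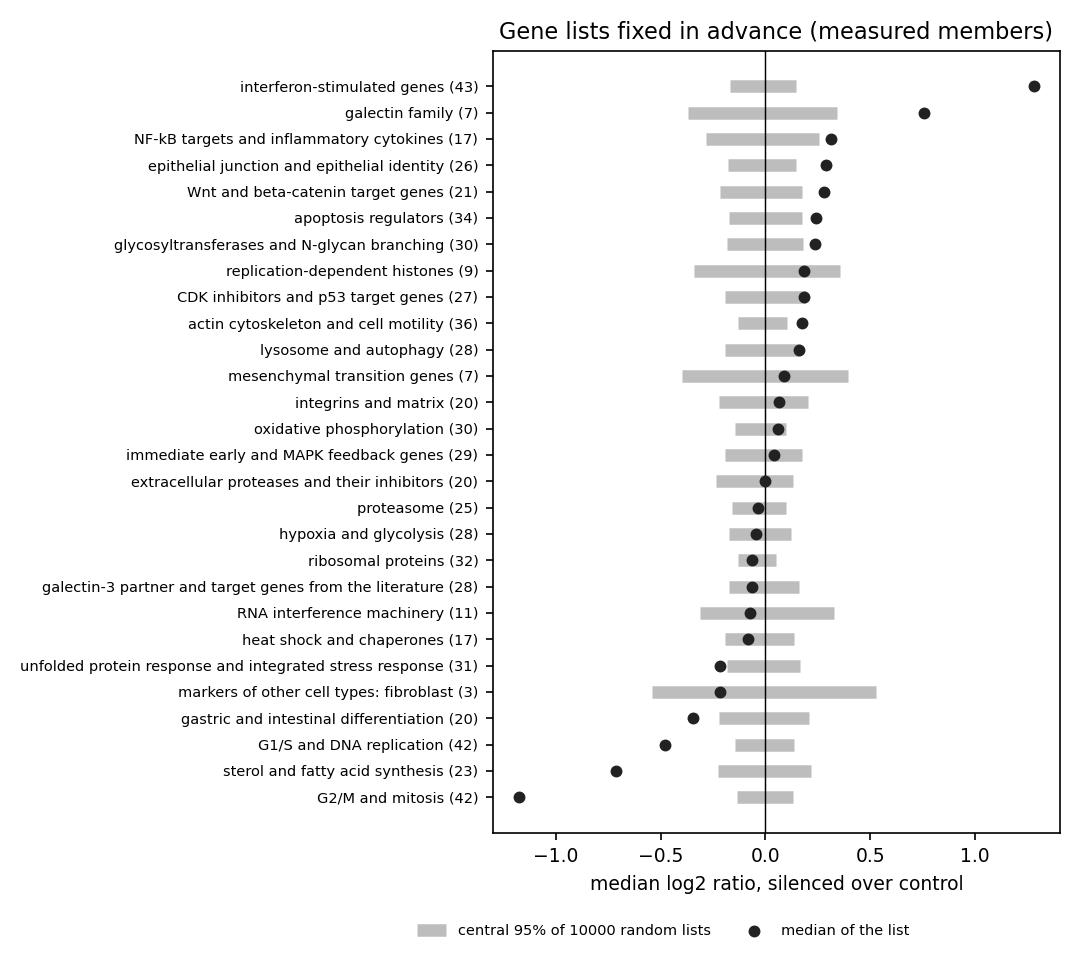
Median log2 ratio (silenced over control, points) of the 28 gene lists with at least 3 measured members, whose numbers stand in brackets, with grey bars for the central 95% of 10000 random lists matched on signal. Of these, 8 medians lie above and 5 below their bars, from 1.28 for interferon-stimulated genes to -1.18 for the G2/M list, and the medians of the galectin and NF-kB lists change sign under some other settings, as does that of the actin list under a scaling that shifts all genes alike.

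With the reported settings the remaining lists lay within the central 95% of their random lists, with medians from -0.22 for fibroblast markers to 0.18 for histones. Of 27 cyclin-dependent kinase inhibitors and p53 targets 3 were at least 2-fold higher, TP53I3 by 3.13-fold, CDKN2B by 2.38-fold and CDKN1C by 2.01-fold, with a median of 0.18, or 0.20 relative to all genes. Setting the poly-A controls equal turned it to -0.05, but left it at 0.20 relative to all genes. It lay outside the central 95% with the median of a gene's probe sets, above 99.9% of random lists, and with the lowess curve on probe sets above the floor, above 98.4%. Of 20 extracellular proteases and inhibitors, MMP7 was 5.04-fold higher, the plasminogen activator PLAT at least 3.10-fold and the urokinase receptor PLAUR 2.32-fold, while MMP1 was 4.96-fold lower. Of the 20 genes 10 had a ratio above 0, 5 a ratio under 0, and 5 a bound with no direction that stays in the median. The list median was 0.00, but under 5 alternatives it lay outside the central 95%, above 97.8% to 99.35% of random lists. These were the other 3 choices of floor, the offset, and leaving out _s_at and _x_at probe sets. Of 28 lysosome and autophagy genes WIPI1 was 2.89-fold and GABARAPL1 2.18-fold higher, with a median of 0.16, or 0.17 relative to all genes. Setting the poly-A controls equal turned it to -0.07, but left it at 0.17 relative to all genes. This list was close to the bound. It lay above 97.6% to 99.65% of random lists under 5 alternatives (quantile normalization, both lowess curves, a floor 2 times higher and the offset) and above 65.2% with the median of a gene's probe sets. Of 29 immediate early and MAPK feedback genes PHLDA1 was 2.94-fold and JUN 2.14-fold higher, and ETV4 was 2.69-fold lower. EGR1 was 2.05-fold lower on 1 of 3 probe sets, while the others had log2 ratios of -0.18 and -0.47. ITGB8 was 5.24-fold higher among 20 integrin and matrix genes, the matrix protein TGFBI at least 5.03-fold among 7 mesenchymal genes, and the glucose transporter SLC2A1 3.40-fold among 28 hypoxia and glycolysis genes. Another SLC2A1 probe set had a log2 ratio of 0.62. Of 9 replication-dependent histone genes H2AC6 was 2.92-fold and H2BC5 2.45-fold higher and H4C5 2.48-fold lower. The H2BC5 probe sets are all of the cross-hybridising _x_at kind. The histone median lay above 99.5% of random lists with a floor 2 times higher, and changed sign under 5 of 12 other settings. Among these was the setting with the poly-A controls set equal, which shifts every gene alike. Among 30 genes of oxidative phosphorylation SDHA was 2.80-fold lower, on a probe set that can also bind related sequences. Other probe sets of genes named above stopped short of 2-fold in the same direction, with log2 ratios of -0.88 for BIRC5, 0.77 for CDKN2B, -0.93 for CLDN1, 0.79 for GCNT1 and -0.85 for MAN1A1.

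Housekeeping lists differed little. None of 32 ribosomal protein genes, 25 proteasome genes, 17 heat shock genes or 11 genes of the RNA interference machinery passed 2-fold in either direction. The largest ratios among the ribosomal proteins were for RPLP2, at least 1.96-fold lower with signals of 214.4 and 53.6, and RPL22, with a log2 ratio of 0.26. Another RPL22 probe set gave 0.24, while its stronger _x_at probe sets went the other way, with -0.18, -0.13 and -0.13. The proteasome subunits PSMD11 and PSMA7 were 1.41-fold and 1.27-fold lower. HSPH1 was 1.68-fold lower and HSPB1 1.65-fold higher, TNRC6A 1.34-fold higher with other probe sets that went the other way, and PRKRA 1.23-fold lower. Markers of other cell types were mostly under the floor. Of 10 fibroblast markers 3 were measured, of which PDGFRA was 2.49-fold lower on 1 probe set and had a log2 ratio of 0.70 on another. Of 8 endothelial markers only PECAM1 was measured, with signals of 127.4 and 121 near the floor. The ratio of signals at the 3' and 5' ends, a sign of RNA quality, was 0.980 in the control and 0.936 after silencing for GAPDH, and 1.14 and 1.13 for ACTB.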

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

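The count of probe sets without a single gene name was the only result of this kind, and counting it was chosen only after the main values were seen. These probe sets enter no gene count or gene list, and a signal was present in them. Leaving out the control probe sets of the array, there were 13522 such probe sets, of which 3501 were above the floor on at least 1 array. Among these 97 were at least 2-fold higher and 105 at least 2-fold lower on the silenced array. That is 5.77%, beside 6.30% of the probe sets with 1 gene name. No explanation was tested for these probe sets, and which genes they measure was not analysed here.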

How the results depend on the processing

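Scaling on the hybridization controls or on the poly-A controls was chosen after the data were seen. The lowess curve fitted only on probe sets above the floor was the first form of the planned lowess. The curve over all probe sets replaced it once its counts were seen, so that choice was also made after the data were seen. No paired analysis was possible because each group holds 1 array. The LGALS3 ratio moved by less than the spread between probe sets of one gene under 11 alternatives, and had no value without _s_at and _x_at probe sets, since the remaining probe set was under the floor. Of 104 other named genes, 1112 of 1217 values moved by less than that spread, 105 by more and 0 changed sign among genes past 2-fold. Part of this was fixed in advance. Median centring and scaling on the hybridization or poly-A controls shift every gene by a constant smaller than that spread. Another floor, or none, leaves the ratio of a gene above it on both arrays unchanged. Signals near the floor are a further limit, since a gene there has a bound or no ratio.

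Counts of higher and lower genes stayed within 1.5 times the reported 348 and 323 under 8 alternatives in each direction. They were 2466 and 2459 without a floor, 1117 and 1091 at 1.5-fold, 74 and 60 at 3-fold, and 143 and 126 when 2 or more probe sets had to go the same way, all by construction. With the floor as an offset 204 genes were higher. Hybridization controls at 0 gave 576 and 183 (75.9% higher, median of all genes 0.17), and poly-A controls at 0 gave 186 and 633 (22.7% higher, median -0.25). The lowess above the floor gave 986 lower genes and 284 higher (22.4% higher). By construction it rests on probe sets kept by unequal floors. Scaling on either kind of control shifts every ratio by a constant, and the offset draws each ratio of signals toward that of the floors. Those counts therefore also changed by construction. Why the lowess above the floor gave more lower genes was not tested.

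List medians are given here relative to the median of all measured genes. Of 362 values, 312 stayed the same, 48 moved and 2 reversed. Part of this was fixed in advance. Median centring and scaling on the hybridization or poly-A controls shift every gene alike, so no value relative to all genes could move there. Random lists not matched on signal change only the lists' bounds and not the value. With a floor 2 times higher the galectin family reversed to -0.22 and NF-kB targets to -0.049, while proteases moved to 0.29, interferon-stimulated genes to 1.13, immediate early genes to 0.16, histones to 0.55 and lysosome genes to 0.22. With the array median as the floor proteases were at 0.27, differentiation genes at -0.18, immediate early genes at 0.16, histones at -0.0027 and fibroblast markers at 0.40. Without a floor proteases were at 0.26, differentiation genes at -0.16, immediate early genes at 0.16, glycosyltransferases at 0.19, histones at -0.00056 and fibroblast markers at -0.48. With the offset proteases were at 0.21, G2/M genes at -1.08, interferon-stimulated genes at 1.17 and lysosome genes at 0.19. Quantile normalization put ribosomal proteins at 0.0026 and lysosome genes at 0.20, and the lowess over all probe sets put lysosome genes at 0.19. The median of probe sets put differentiation genes at -0.21, p53 targets at 0.34, glycosyltransferases at 0.17 and lysosome genes at 0.032. Without _s_at and _x_at probe sets the galectin family was at 0.32, literature genes at 0.037, proteases at 0.29, actin genes at 0.15, mesenchymal genes at -0.12, G1/S genes at -0.54, G2/M genes at -1.08, apoptosis regulators at 0.17 and NF-kB targets at 0.13. The lowess above the floor put the galectin family at 0.019, actin genes at 0.29, p53 targets at 0.26, NF-kB targets at 0.060, immediate early genes at 0.17, heat shock genes at 0.021, ribosomal proteins at 0.076, histones at -0.23, oxidative phosphorylation at 0.17, proteasome genes at 0.066, lysosome genes at 0.29 and fibroblast markers at -1.16. The cause of these moves was not tested. Relative to all genes, the interferon, G1/S, G2/M and sterol lists kept their side of 0 under every alternative run. This was not particular to them. Not taken relative to all genes, the Wnt, epithelial junction, apoptosis and glycosyltransferase medians also kept their side of 0 under 12 settings. So did those of the differentiation and unfolded protein response lists.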

Other observations

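The lists and the genes in the first 2 paragraphs were chosen only after the gene values were seen, as were the list of LXR targets and the tests of leukocyte markers, of double-stranded RNA and of the gap between the G2/M and G1/S lists. Further genes of chromosome segregation were lower on the silenced array. All 27 measured genes of a further list, mainly for kinetochore and spindle parts outside the G2/M list, had a ratio under 0, and 9 were at least 2-fold lower. Their median log2 ratio was -0.93. The separase gene ESPL1 was 3.20-fold lower, GTSE1 2.51-fold and the kinesin KIF18A 2.28-fold. Of 13 genes of homologous recombination and Fanconi repair 3 were at least 2-fold lower, XRCC2 by 3.30-fold, BRCA1 by 2.70-fold and FANCI by 2.25-fold, while other probe sets had log2 ratios of -0.31 for BRCA1 and -0.74 for FANCI. XRCC2 rested on a single probe set of the cross-hybridising _x_at kind, with a silenced signal of 114.5 near the floor. The median of the 13 genes was -0.53. Some members of both lists had been seen to be lower before the lists were drawn up, so these medians are no test of the pattern.

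Other single genes stood apart from the lists around them. ID1, like ID3 an inhibitor of basic helix-loop-helix factors, had signals of 17577 and 4699.9 and was 3.74-fold lower. The median of 7 genes of the BMP and SMAD pathway, with ID3 left out after its value was seen, was -0.10. TXNIP, an inhibitor of glucose uptake, was 2.96-fold higher and its relative ARRDC4 at least 2.54-fold. KLHL24 was 2.79-fold higher, although 2 of its other probe sets had log2 ratios of 0.30 and 0.073, and the 9 FOXO target genes that include it, with TXNIP left out after its value was seen, had a median of 0.04. Of 12 YAP and TEAD target genes AMOTL1 was 3.24-fold lower, and the list median was 0.25. KRT80 was 2.25-fold higher among 7 genes of stratified epithelium, whose median was 0.11 with SCEL and ANXA9 left out after their values were seen. The interferon-induced GBP1 was at least 3.80-fold higher, whereas none of 15 genes of MHC class I presentation passed 2-fold and their median was 0.04.

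Interferon-stimulated genes were higher on the silenced array, with a median log2 ratio of 1.28. The values argued against the scaling between the arrays as the whole cause, since the lowest median over 6 scalings was 1.05. They argued less firmly against leukocytes in the silenced culture as the source of these transcripts, since 0 leukocyte markers were above the floor and at least 2-fold higher. Of 10 markers 9 were under the floor on both arrays, and LYZ was so high in both that it would hide a small share of such cells, so a few leukocytes that release interferon are not excluded. What stays open is whether the loss of galectin-3 or the double-stranded RNA used to silence it could account for the genes, since such RNA is a known inducer of interferon. With no array of a second galectin-3 siRNA or of a rescue these cannot be told apart. The treatment of the control cells is also not given in the sources used here.

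Genes of the G2/M list were lower on the silenced array, with a median of -1.18. The values argued against the scaling between the arrays as the whole cause, since the highest median over 6 scalings was -0.997. The G2/M median lay at -0.70 from the G1/S median, outside the -0.19 to 0.19 of random pairs. This gap was examined after both medians had been seen, and genes in random pairs are not chosen as regulated together. It therefore describes an unequal lowering on these arrays and is no independent test against an equal lowering of G1/S and G2/M genes. A smaller share of cells in mitosis after the loss of galectin-3 is a hypothesis that may fit these values, and the share of cells in each phase was not analysed here. An effect of siRNA treatment that does not depend on galectin-3 stays equally open, because no second siRNA and no rescue was measured.

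Genes of sterol and fatty acid synthesis were lower, with a median of -0.71. The values argued against the scaling between the arrays as the whole cause, since the highest median over 6 scalings was -0.53. A sterol load in the cells could lower these genes and raise targets of the sterol receptor LXR, of which ABCA1 was 3.59-fold higher. The 5 other LXR targets measured had a median of -0.10, above 34.3% of random lists whose SD was 0.28, so too few genes were measured to tell a sterol load from another cause. The loss of galectin-3 and an effect of the transfection itself both stay open, as untested.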
